A study of Mus musculus with 15 samples.

How the data were processed

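The series holds 15 NG Capture-C samples of 9 groups: control, R1R2_KO and R2R3_KO erythroid cultures with 3 samples each, and R1_KO, R2_KO, R3_KO, Rm_KO, R4_KO and ES cells with 1 each. Per the labels' protocols, fetal liver cells of embryonic day 12.5 were expanded for 5 to 7 days, depleted of Ter119-positive cells and differentiated for 18 hours, and 3C libraries were cut with DpnII and captured in 2 rounds with oligonucleotides. The labels give all fetal liver samples the strain F1 C57Bl6/CBA, and replicates are named biological there. Whether a number marks a shared litter or day is not given, so p-values measure the spread between these samples only. The edgeR p-values share that spread across the fragments, or the few regions and blocks, of a viewpoint. Very small ones therefore rest on more than the 3 against 3 libraries of a contrast. Per the file headers, R1R2_KO has the sample numbers 1 to 3, control 4 to 6 and R2R3_KO again 1 to 3; whether this marks a separate run is not given in the sources used here. The ES sample carries the fetal liver protocol text, so how these cells were grown is not given in the sources used here; its label names Slc25a38 where the others name Slc25a37, and its column in the Slc25a37 table was used.

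The authors deposited 6 tables of raw read counts per DpnII fragment, not scaled to depth, in mm9; per the submitters' processing notes, Trim Galore and Bowtie were used, with versions not given in the sources used here. For each viewpoint, 1 table holds control and the knockout pairs and another the single knockouts and ES cells. No control library lies in the second table, so values set across tables compare libraries that were tabulated apart. Each table of the controls holds 7 further columns that match no sample here, and these were not used. How reads shared by the near-identical Hba-a1 and Hba-a2 copies were counted is not given in the sources used here.

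Viewpoints were taken as the gaps of at least 1500 bp that the tables leave at the captured promoters. Library size was the reads on the viewpoint chromosome more than 2 kb from a viewpoint. Regions were fixed before the data were examined, in mm9 and approximately, and snapped to fragments by midpoint. The reference gene table is GRCm38.p6, another build, and served only for names and neighbour order. Intervals are Wilson 95% intervals; PCR reads carry no molecular identifiers, so intervals and the floor of 3 reads for a zero count cover counting error only. Coverage of the 9 replicated libraries is 12089 to 95677 chromosome reads per viewpoint.

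The element blocks needed a rule other than the one fixed beforehand. That rule, fragments with 0 reads in every library of the knockout, found 1 fragment of R2 and 2 of R3 in R2R3_KO, none in R1R2_KO and none in any single knockout. After the counts were seen, 2 other rules were tried. The first, under 30% of the control mean in every library of the knockout, was not kept: it gave no block in R1_KO and rests on the libraries being compared. The second, under 50% of the mean of the other single knockouts in the library lacking the element, was used because it covers all 5 elements and does not use the replicated knockout libraries. It makes the depletion of each block in its own single knockout circular. Its 50% was picked with the ratios in view. The other 2 rules were run as alternatives.

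Fragments within 500 kb with 90 or more reads over the 9 libraries were tested with edgeR 4.0.16 (quasi-likelihood, group as the only term, all 9 libraries in 1 fit, Benjamini-Hochberg at 0.05 within a contrast) in R 4.3.3. Regions and blocks of a viewpoint entered 1 such fit on summed counts, adjusted over regions and contrasts; blocks deleted in either group were adjusted apart. Fragments of deleted blocks were not adjusted apart. At Hba the adjustment ran over all 403 fragments, and those in deleted blocks were then left out of the counts. Their small p-values loosen the threshold for the rest, and an adjustment without them was not run. Exact two-sided permutation tests of 3 against 3 cannot go below 0.1. Named fragments are the 10 lowest and 10 highest past 0.05 in each Hba contrast and the 3 lowest and 3 highest elsewhere, and the text prints some of them. Python 3.11.15 with scipy 1.17.1 made the other values.

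On simulated counts with 200 changed fragments over the 3 viewpoints, the edgeR step recovered 34.1% of log2 changes of 0.5 and 79.5% of 1 at Hba, 3.1% and 38.7% at Hbb, and 24.0% and 87.5% at Slc25a37, for R1R2_KO against control; a first version, which limited the changed fragments to a share of those tested, was replaced. Between replicates, chi-square over its degrees of freedom ran from 1.00 to 7.98 over 27 pairs. The same pair, R2R3_KO libraries 1 and 3, was lowest at each viewpoint: 1.00 at Slc25a37, 1.51 at Hba and 1.61 at Hbb. Since it lay above 1 at Hba and Hbb, no library was counted as a duplicate.

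Alternatives fixed beforehand were DESeq2 1.42.0, limma 3.58.1, TMM factors, whole-genome and outside-region library sizes, filters of 1 and 450 reads, 5 kb bins, a 5 kb exclusion zone, only the 6 libraries compared, the replicate number as a block, blocks widened by 1 kb, and leaving out each library. The local scale (reads within 500 kb), the 30% block rule, the use of the preset block rule as a comparison, the fit without R1R2_KO library 1, the single-knockout cluster less the Rm and R4 blocks, and the locus control region of R1_KO without fragments that ES cells lack were chosen after seeing the data.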

Results

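Chromatin contacts of 3 promoter viewpoints were measured by NG Capture-C, a method that joins neighbouring DpnII fragments by ligation and enriches the products with oligonucleotides for chosen promoters. The viewpoints were the α-globin genes (Hba-a1 and Hba-a2, here Hba), the adult β-globin genes (Hbb-b1 and Hbb-b2, here Hbb) and Slc25a37, which encodes the mitochondrial iron importer of red cell precursors. Of 15 samples, 14 were erythroid cultures grown from mouse fetal liver and 1 was an embryonic stem (ES) cell line, E14. The α-globin genes are controlled by a group of upstream elements called R1, R2, R3, Rm and R4. Control cells, cells lacking R1 and R2 (R1R2_KO) and cells lacking R2 and R3 (R2R3_KO) had 3 libraries each. Cells lacking a single element (R1_KO, R2_KO, R3_KO, Rm_KO, R4_KO) and ES cells had 1 library each, so their values have no replicate check. The 9 replicated libraries held 66880 to 138216 reads at Hba, 45301 to 99096 at Hbb and 18212 to 47852 at Slc25a37. The 6 unreplicated libraries were deeper, with 386214 to 713934 reads at Hba. Values below are reads per 100000 reads of the viewpoint chromosome, leaving out 2 kb around each viewpoint, with SD and n = 3 unless stated, and all coordinates are mm9.

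The deleted elements lost most of their contact in the libraries labelled as lacking them, R1 least completely. In R1R2_KO the R1 block (chr11, 32144385 to 32146566) kept 25.6% ± 2.55 (SD, n = 3) of the control value and the R2 block (chr11, 32150268 to 32151881) kept 11.8% ± 1.85. Both R1 fragments kept 20.9% to 31.3% of control in each R1R2_KO library, so neither neared 0. The cluster fragment next to the R1 block, 32146567 to 32146860, fell from 525 in control to 188 in R1R2_KO. The R1 fall is thus a weaker check of the label than those at R2 and R3. In R2R3_KO the R2 block kept 10.3% ± 0.39 and the R3 block (chr11, 32155867 to 32157248) kept 8.47% ± 2.34. The R2 fragment at 32150623 to 32151061 held 0 reads in each R2R3_KO library and 22, 15 and 22 reads in the R1R2_KO libraries. Block ends follow a rule set after the counts were seen, and the single knockouts define them. Set against the control mean, which lies in another table, the single knockouts kept 41.7% for R1 in R1_KO, 18.9% for R2 in R2_KO, 31.5% for R3 in R3_KO, 25.6% for Rm in Rm_KO and 25.5% for R4 in R4_KO, values that are low by construction.

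Without R1 and R2 the α-globin promoters lost contact with the rest of their enhancer cluster. The cluster (chr11, 32139865 to 32170701, blocks lacking in either pair left out) fell from 20831 ± 515 in control to 13046 ± 510 in R1R2_KO, a log2 change of -0.68 (SE 0.05, edgeR adjusted p = 4.53e-20). Contacts among the α-globin genes (32170702 to 32204979) fell from 28082 ± 1748 to 21154 ± 1046 (log2 change -0.41, adjusted p = 7.81e-12). The exact permutation p, which rests on 3 against 3 libraries alone, was 0.1 for both, the smallest possible. Of the remaining elements, R3, which lies outside the cluster sum, fell by a log2 change of -0.59. Rm (-0.52) and R4 (-0.77) fell as parts of that sum. Outside the cluster the far upstream region (31949955 to 32079920) rose by 0.45, the upstream genes (32080071 to 32135979) by 0.18 and the downstream region (32204980 to 32320310) by 0.25. In the GRCm38.p6 gene order the genes on the upstream side of the α-globin genes include Rhbdf1, Mpg and Nprl3. These 3 rises are relative to all chromosome reads, and the same regions gave -0.11, -0.38 and -0.31 when reads outside all regions set the scale. With reads within 500 kb as the scale (local scale, chosen after seeing the data) the cluster gave -0.42, the α-globin genes -0.15, R3 -0.33, Rm -0.27 and R4 -0.52, and the 3 rises were 0.71, 0.43 and 0.50. With reads outside all regions the cluster gave -1.23, the α-globin genes -0.97, R3 -1.14, Rm -1.07 and R4 -1.33.

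At single fragments, 108 of 398 tested fragments within 500 kb passed 0.05 in R1R2_KO against control, 89 lower and 19 higher. The adjustment also included 5 fragments of deleted blocks, all past 0.05. The 10 strongest falls all lay in the enhancer cluster. The fragment at 32146567 to 32146860 fell most (log2 change -1.47, SE 0.13, adjusted p = 7.42e-15), followed by 32149606 to 32149640 (-1.28) and 32149641 to 32149927 (-1.24). The lowest of these begins next to the R1 block, which ends at 32146566. Another of the 10, 32150164 to 32150267 (-1.03), ends next to the R2 block. Block ends follow a rule set after the counts were seen, and the cluster sum holds both fragments. Whether a deletion reaches into them was not tested. Of the 10 strongest rises, 7 lay in the downstream region, led by 32260138 to 32260963 (1.75, SE 0.52, adjusted p = 0.00725). The balance of directions follows the scale: with reads within 500 kb as the scale 62 fragments were higher and 40 lower, and TMM factors gave 27 and 61. Reads within 500 kb include the deleted blocks and the cluster, so their loss lowers this scale and raises other fragments in the knockouts. Chromosome reads include them too, as a smaller share. In bins of 5 kb, where distant positions gather enough reads to be tested, 116 of 188 bins were higher and 11 lower.

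**Figure D1:**
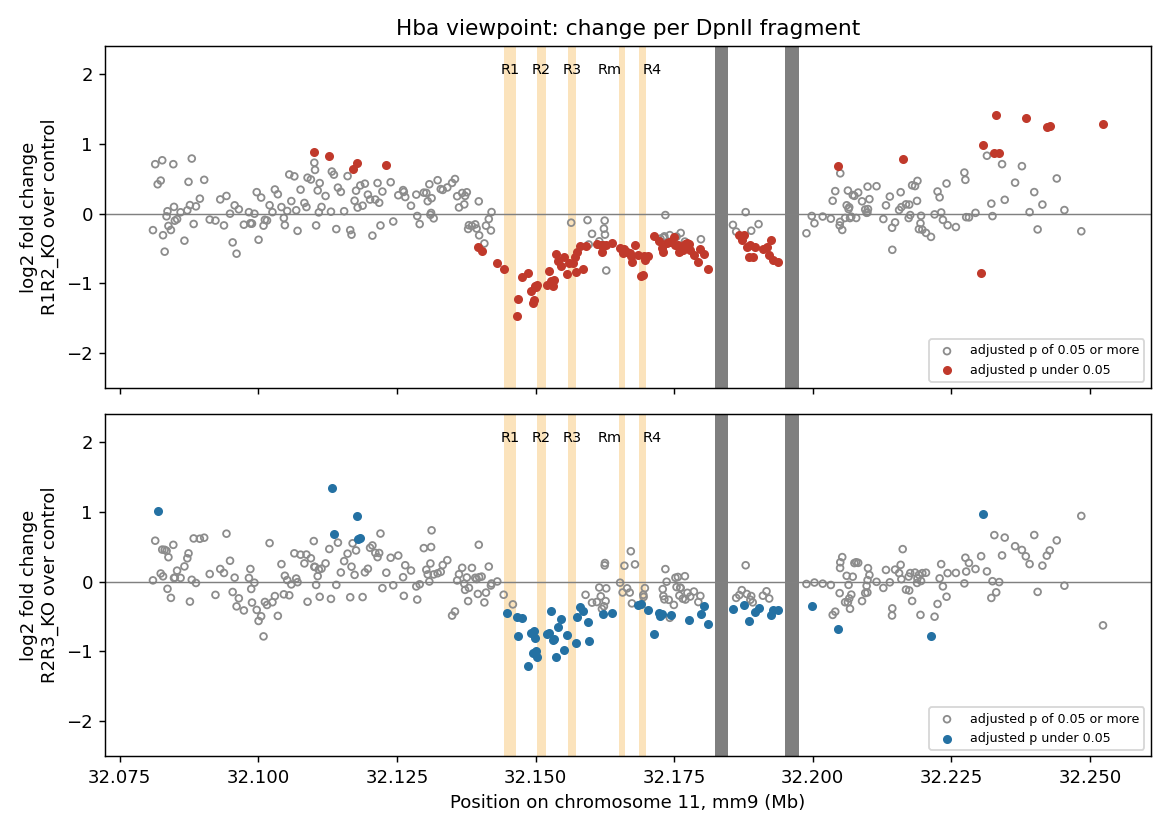
Log2 fold change of each tested DpnII fragment from the Hba viewpoint (vertical axis) by position on chromosome 11, mm9, in Mb, for R1R2_KO (top) and R2R3_KO (bottom) over control, 3 libraries per group. Filled points have an adjusted p under 0.05, orange bands are the element blocks, grey bands the viewpoints, and fragments of blocks lacking in the knockout are not drawn; the 10 strongest falls of each knockout lie in the enhancer cluster, with a lowest value of -1.47 in R1R2_KO and -1.21 in R2R3_KO.

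Without R2 and R3 the same cluster fell less. It reached 15997 ± 127 in R2R3_KO (log2 change -0.38 from control, SE 0.05, adjusted p = 9.75e-11), and the α-globin genes reached 23176 ± 402 (-0.28, adjusted p = 2.55e-07). The exact permutation p was 0.1 for both. R1 fell by a log2 change of -0.38 (adjusted p = 0.00139) and R4 by -0.21 (adjusted p = 0.0148), while Rm gave 0.03 (adjusted p = 0.759). The far upstream region rose by 0.55 and the upstream genes by 0.15, and the downstream region gave 0.10 (adjusted p = 0.0824). In the same libraries regions at the other viewpoints fell by a like amount: the Hbb locus control region changed by -0.36 and the Slc25a37 upstream region by -0.42. The table headers number the R1R2_KO libraries 1 to 3, the control libraries 4 to 6 and the R2R3_KO libraries again 1 to 3; if that marks a separate run, run and group cannot be told apart in any comparison of R2R3_KO. The log2 change of the Hba cluster less the mean of those 2 regions was 0.0068 (SE 0.07) in R2R3_KO and -0.53 (SE 0.07) in R1R2_KO. These SEs treat the viewpoints as independent, though all come from the same libraries. The difference was computed with chromosome reads only, and reads outside all regions shifted the viewpoints by unequal amounts. With the local scale the cluster in R2R3_KO gave -0.19 (adjusted p = 5.26e-07), the α-globin genes -0.08, R1 -0.19 and R4 -0.02, and Rm (0.22) and the downstream region (0.29) passed as rises. The call at R4 was also lost without control library 2 (-0.16) or 3 (-0.15), with limma (-0.20) and under the 30% block rule (-0.27). The exact permutation p at R4 was 0.4. The rise of the upstream genes turned to -0.28 with reads outside all regions as the scale, which ended the far upstream call (0.11). That scale shifts the Hba regions by like amounts, so it makes the falls of the cluster and the α-globin genes larger. The rise of the upstream genes was not called with the whole-genome scale (0.10), the 5 kb exclusion zone (0.10) or without R2R3_KO library 1 (0.13).

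For R2R3_KO against control, 60 of 396 fragments passed 0.05, 52 lower and 8 higher. The adjustment also included 7 fragments of deleted blocks, all past 0.05. The 10 strongest falls lay in the enhancer cluster, led by 32148396 to 32148902 (log2 change -1.21, SE 0.16, adjusted p = 6.78e-09) and 32150164 to 32150267 (-1.08). The latter ends next to the R2 block, and whether the deletion reaches into it was not tested. Of the 8 rises, 6 lay in the upstream genes, with 32113266 to 32113281 at 1.34 (SE 0.42, adjusted p = 0.0178). The rises at 32230644 to 32230730 and 32117787 to 32118068 passed narrowly (edgeR adjusted p = 0.0498 each). They may not pass without the deleted fragments in the adjustment. The count dropped to 33 without R2R3_KO library 2 and to 38 without library 3, and with the local scale it split into 23 higher and 22 lower. In bins of 5 kb 42 were higher and 9 lower.

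Compared directly, the R2R3_KO libraries, which the headers number again from 1, held more contact with the cluster than the R1R2_KO libraries. The cluster was higher by a log2 difference of 0.30 (SE 0.05, adjusted p = 1.06e-07), the α-globin genes by 0.13 (adjusted p = 0.00742), Rm by 0.55 (adjusted p = 1.58e-06) and R4 by 0.56 (adjusted p = 7.26e-08). The exact permutation p was 0.1 for each of these. The downstream region was lower by 0.15 on the log2 scale (adjusted p = 0.00925), and the far upstream region (0.09) and the upstream genes (-0.03) did not pass. Of 394 fragments 33 passed, 24 higher and 9 lower in R2R3_KO. A further 9 fragments of deleted blocks, 8 of them past 0.05, stayed in the adjustment. Calls near 0.05 may therefore not hold without them. The fragment at 32167110 to 32167265, between Rm and R4, was higher by 1.04 (SE 0.18, adjusted p = 6.28e-06), and 32204332 to 32204781, inside the α-globin gene region, was lower (-1.36, SE 0.21, adjusted p = 7.61e-07). With the local scale the α-globin genes gave 0.07 and the upstream genes passed at -0.09. The call at the α-globin genes was lost with the whole-genome scale (0.03) and with limma (0.13), and that of the downstream region with reads outside all regions as the scale (-0.02) and without R1R2_KO library 3 (-0.11), R2R3_KO library 1 (-0.13) or R2R3_KO library 2 (-0.14). The whole-genome scale gave 10 fragments higher and 14 lower, TMM factors 19 and 15, the local scale 19 and 16, and bins of 5 kb 4 and 12.

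The β-globin locus, on another chromosome, served as a viewpoint at which no element was targeted. In R1R2_KO no region passed 0.05: the locus control region (chr7, 110994810 to 111023773), the distal enhancer of the β-globin genes, measured 22461 ± 1490 against 24151 ± 1362 in control (log2 change -0.11, adjusted p = 0.253), and the embryonic genes gave -0.13. In R2R3_KO the locus control region fell to 18814 ± 1127 (-0.36, SE 0.08, adjusted p = 5.03e-04) and the embryonic gene region (110980132 to 110994809) to 5855 ± 354 (-0.41, adjusted p = 0.00223). These 2 of 10 tests passed, each with an exact permutation p of 0.1. The 3-prime side, the 3-prime boundary and the 5-prime side gave values from -0.23 to 0.24 in R2R3_KO and did not pass. Without R1R2_KO library 2 the 3-prime side (-0.42) and the 3-prime boundary (-0.43) passed in R1R2_KO, and the boundary passed with limma (-0.34, adjusted p = 0.0202). With the local scale 5 of the 10 passed: in R2R3_KO the locus control region (-0.11, adjusted p = 0.0259), the embryonic genes (-0.16), the 3-prime side (0.49) and the 5-prime side (0.29), and in R1R2_KO the 3-prime boundary (-0.18). The locus control region (0.056) and embryonic genes (0.024) then turned direction in R1R2_KO without passing.

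At single Hbb fragments edgeR called 0 of 339 in R1R2_KO, with 26 at an unadjusted p under 0.05; DESeq2 gave 0, TMM factors 1, no filter on low counts 7, and leaving out R1R2_KO library 1 gave 1. In R2R3_KO 6 fragments passed, all lower, with 111009552 to 111009747 in the locus control region falling from 582 to 291 reads per 100000 (adjusted p = 0.00848). R1R2_KO library 1 lacks most reads at a part of the Hbb fragments, and the R2R3_KO count rose to 64 when this library was not in the fit, an alternative chosen after seeing the data. DESeq2 and TMM factors gave 1 call each. The count was 0 without R2R3_KO library 1, 2 or 3 or control library 2 or 3, and 3 without control library 1.

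At Slc25a37 the upstream region (chr14, 69905816 to 69959889) held the most reads of the 4 regions and fell in both pairs. It measured 37732 ± 2980 in control, 33070 ± 1195 in R1R2_KO (log2 change -0.19, adjusted p = 0.00887) and 28281 ± 611 in R2R3_KO (-0.42, SE 0.06, adjusted p = 7.14e-05). The exact permutation p was 0.1 for both pairs. In R2R3_KO the gene body (69859913 to 69900081) fell by a log2 change of -0.25 while the far side (69759957 to 69859912) rose by 0.38 and the far upstream region (69959890 to 70060563) by 0.34. In R1R2_KO the far upstream region gave -0.12 (adjusted p = 0.0423), and the far side (0.04) and gene body (0.05) did not pass. The upstream call in R1R2_KO was lost with the whole-genome scale (-0.17), and the far upstream call there with that scale (-0.08), the local scale (-0.04), the replicate block (-0.12, adjusted p = 0.0692) and without R1R2_KO library 3 (-0.09) or control library 1 (-0.10) or 2 (-0.11). In R1R2_KO the gene body passed with the local scale (0.13). In R2R3_KO the local scale gave -0.15 upstream, 0.01 at the gene body, 0.64 on the far side and 0.61 far upstream, and reads outside all regions as the scale gave 0.05 on the far side and 0.02 far upstream.

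For R2R3_KO 46 of 225 Slc25a37 fragments passed, 45 lower and 1 higher, with 69946503 to 69946882 lowest at -1.60 (SE 0.39, adjusted p = 7.90e-04). For R1R2_KO 9 passed, 8 lower and 1 higher, with 69944739 to 69945563 lowest at -0.94. DESeq2 gave 6 and 0 calls, and TMM factors 10 and 4. In bins of 5 kb 10 were higher and 14 lower in R2R3_KO, and 3 higher and 2 lower in R1R2_KO. DESeq2 gave 1 higher and 5 lower in R2R3_KO, and in R1R2_KO TMM factors gave 1 higher and 3 lower and the whole-genome scale 0 and 2. The R2R3_KO count was 30 without R2R3_KO library 2 and 29 without control library 2, and the R1R2_KO count was 5 and 2 without R1R2_KO library 2 and 3, and 22, 0 and 2 without control library 1, 2 and 3.

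**Figure D2:**
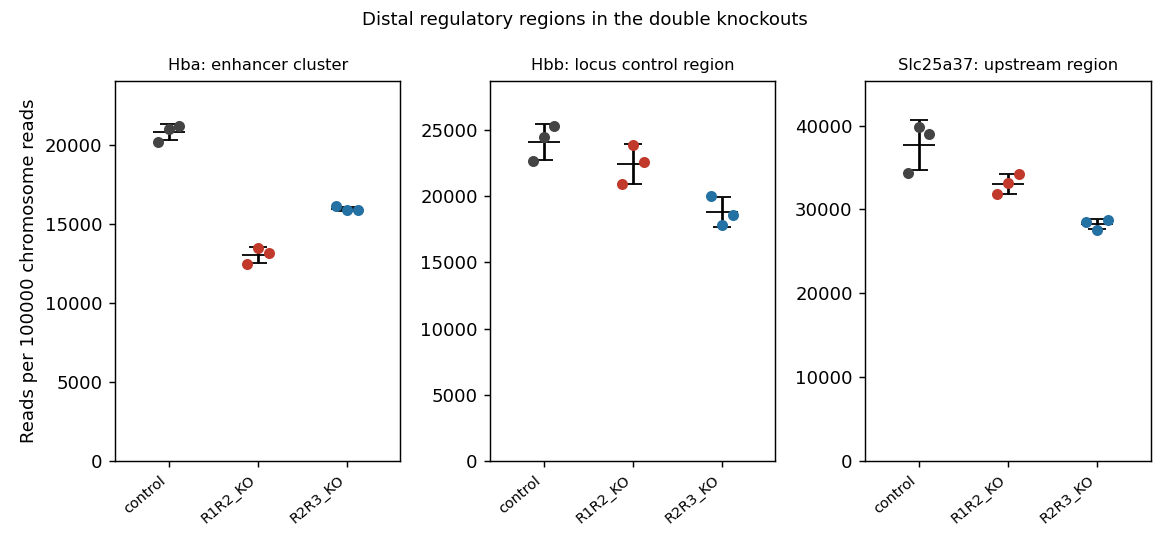
Reads per 100000 chromosome reads (vertical axis, from 0) in the main distal region of each viewpoint; points are libraries, bars are mean ± SD, n = 3. All 3 R2R3_KO libraries lie below all 3 control libraries at each viewpoint, and R1R2_KO is lowest at the Hba cluster, at 13046 against 20831 in control.

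The share of reads near the α-globin viewpoint was lower in both pairs and the share far from it higher. From Hba, the share of all reads 10 to 50 kb away, which holds the deleted blocks, was 22.6% ± 2.43 in control, 16.1% ± 0.45 in R1R2_KO and 16.5% ± 0.23 in R2R3_KO. The share at 100 to 500 kb was 4.21% ± 0.17, 7.04% ± 0.43 and 5.68% ± 0.10. From Hbb, the share at 10 to 50 kb was 20.4% ± 3.18 in control, 17.5% ± 2.30 in R1R2_KO and 14.5% ± 0.79 in R2R3_KO, and from Slc25a37 it was 25.0% ± 2.78, 23.6% ± 0.80 and 19.2% ± 0.77. The exact two-sided permutation p was 0.1 for both pairs at Hba and for R2R3_KO at Hbb and Slc25a37 at 10 to 50 kb, the smallest that 3 against 3 libraries allow, and 0.3 and 0.4 for R1R2_KO at Hbb and Slc25a37. Over 5 Mb away the share rose from each viewpoint in both pairs. From Hba it was 13.1% in control, 19.0% in R1R2_KO and 17.6% in R2R3_KO. From Hbb these were 16.4%, 18.0% and 19.2%, and from Slc25a37 15.1%, 16.9% and 20.3% (exact permutation p = 0.1 each). At 100 to 500 kb R1R2_KO gave 3.83% against 3.98% at Hbb and 3.37% against 3.24% at Slc25a37 (exact permutation p = 0.6 and 0.5).

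Among single-element knockouts and relative to chromosome reads, the α-globin promoters contacted the cluster least in R1_KO, a library that lay below the mean of the others at the other viewpoints too. The cluster measured 16654 in R1_KO (Wilson 95% interval 16543 to 16766), 88.6% of the mean of the other single knockouts. It was 107.7% in R2_KO, 102.8% in R3_KO, 105.8% in Rm_KO and 95.6% in R4_KO, sums that hold the Rm and R4 blocks and so the deleted block of the last 2. Less both blocks, an alternative chosen after seeing the data, R1_KO gave 86.9%, R2_KO 101.7%, R3_KO 99.3%, Rm_KO 110.3% and R4_KO 102.4%. R1_KO measured 88.0% at the Hbb locus control region and 90.1% at the Slc25a37 upstream region, and R2_KO 126.5% and 122.9%. R1_KO lacks most reads at 22 Hbb fragments (110954233 to 111060063) that ES cells lack; 3 of these lie in the locus control region, which gave 89.5% without them, an alternative chosen after seeing the data. The log2 level of the Hba cluster less the mean of those 2 regions was lowest in R2_KO (-0.71) and was -0.55 in R1_KO, against -0.53 ± 0.06 in control, which lies in another table. With the whole-genome scale R4_KO was lowest, at 84.0% against 93.5% in R1_KO, and less both blocks at 90.1% against 91.9%. With reads outside all regions as the scale R1_KO gave 84.3%, R2_KO 116.9% and Rm_KO 114.7%. The intervals cover counting error only.

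ES cells, which do not make globin, had fewer contacts with each distal region relative to chromosome reads. At Hba 82.8% of their reads lay on the viewpoint chromosome, against 54.3% to 68.7% in the single knockouts. A whole-genome scale therefore makes these falls smaller. The Hba cluster measured 7092 (7026 to 7160), 38.6% of the single-knockout mean, the Slc25a37 upstream region 53.5%, and the Hbb locus control region 5168 (5080 to 5258) against a lowest single-knockout value of 20231. The α-globin genes kept 78.5%. The label of the ES sample names Slc25a38 where the others name Slc25a37, and its reads in the Slc25a37 table lay on chromosome 14 to 81.7%. More distant contacts were higher in ES cells: 406.7% of the single-knockout mean at the Hba far upstream region, 229.8% downstream, and 209.1% at the Slc25a37 far upstream region.

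**Figure D3:**
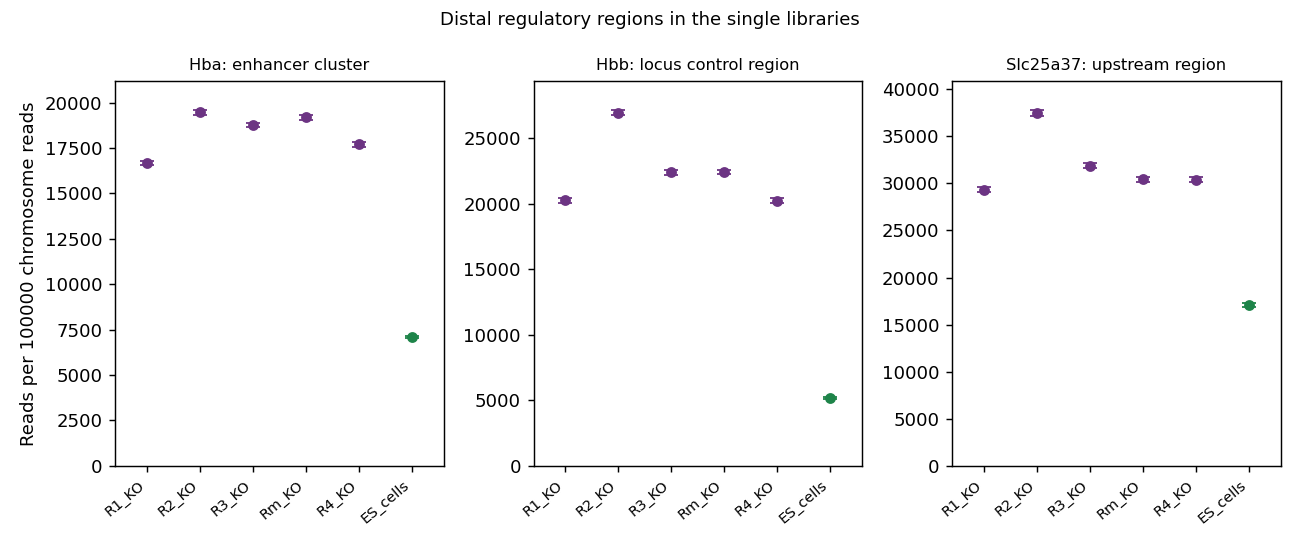
Reads per 100000 chromosome reads (vertical axis, from 0) in the main distal region of each viewpoint in the 6 libraries without replicates; bars are Wilson 95% intervals of counting error. ES cells are lowest in each plot, at 7092 for the Hba cluster, and R2_KO is highest in each.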

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

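The tests of residual reads in this part were all chosen after the result was seen.

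Some libraries held reads at fragments that the R2R3_KO libraries lacked entirely. At the R2 fragment (chr11, 32150623 to 32151061), with 0 reads in each R2R3_KO library, the R1R2_KO libraries 1, 2 and 3 held 22, 15 and 22 reads, which is 3.60%, 5.13% and 6.55% of control, and R2_KO held 109 (6.54%). At the 2 R3 fragments (32156382 to 32156889) R3_KO held 543 reads, 25.0% of the control mean, which lies in another table. What singled them out is a signal above the floor of 3 reads where the named element should be gone.

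Reads or cells of other libraries could bring such reads. A set of Hbb fragments that ES cells nearly lack gives an upper limit on them where a library lacks that set too. In R1R2_KO library 1 that set (22 fragments, spread over chr7, 110954233 to 111060063) held 11.4% of control (9.57% to 13.5%). This lies above the 3.60% (2.38% to 5.45%) at the R2 fragment, so this source stays open. The limit does not show that the reads are foreign. In R1_KO the set held 20.5% of the other single knockouts (18.9% to 22.1%), below the 40.1% (38.3% to 42.0%) at the R1 block, which argues against foreign reads as the whole source there. In R3_KO the set held 55.0% of control, so it sets no limit on foreign reads there. Cells that keep an allele, or deletion ends that differ between alleles, were not tested and stay open, and the R1 block may reach past the deletion.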

How the results depend on the processing

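The local scale, the 30% block rule, the rerun of the preset no-read rule as a comparison, the fit without R1R2_KO library 1, the cluster less the Rm and R4 blocks and the locus control region without fragments that ES cells lack were chosen after seeing the data. Of 41 single region and block results, 27 passed 0.05; 14 of these kept their direction and call in all alternatives run and 5 turned direction in some. Over other settings, 247 values kept direction and call, 22 reversed, 9 gained and 15 lost a call; with a library left out these were 227, 6, 4 and 9. Of the main counts and values under other settings, 108 stayed within 1.5 times the count or the spread of the value, 9 counts were higher, 14 lower and 27 values moved; without a library these were 140, 3, 15 and 1. The cause was not tested for any of the changes below. Recovery of simulated changes was lowest at Hbb, not at the shallowest viewpoint, Slc25a37. The simulated counts took their spread from all 9 libraries, R1R2_KO library 1 included. At Hbb that library gave a chi-square over degrees of freedom of 7.98 and 7.57 against the other R1R2_KO libraries, and these gave 1.75. A simulation without that library was not run.

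The replicate numbers were not taken as pairs, since not every same-number correlation lay over 0.1: these ran from -0.05 to 0.22 at Hba, -0.13 to 0.30 at Hbb and -0.19 to 0.17 at Slc25a37, and those of different numbers from -0.18 to 0.073, -0.30 to 0.30 and -0.17 to 0.22. As a hint of pairing, at Hba each control and R1R2_KO library correlated best with its own number (0.22, 0.090 and 0.11), which did not hold at Hbb or Slc25a37. With the replicate block, fragments past 0.05 were 108, 60 and 43 for the 3 Hba contrasts, 0 and 6 at Hbb and 9 and 43 at Slc25a37. Regions were 5, 4 and 3 at Hba, 2 at Hbb and 5 at Slc25a37, and element blocks 7. The block ended the Slc25a37 far upstream call in R1R2_KO and no other region call.

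Between the knockouts at Hba, the 6 libraries compared gave 54 fragments and bins of 5 kb 16. For Hbb in R1R2_KO, TMM factors gave 1, no filter 7 and the local scale 1. For Hbb in R2R3_KO, DESeq2 gave 1, TMM factors 1, the whole-genome scale 10, the filter at 450 reads 15, the 6 libraries compared 61, the local scale 1 and the fit without R1R2_KO library 1 64. For Slc25a37 in R1R2_KO, DESeq2 gave 0, TMM factors 4, the whole-genome scale 2, no filter 2 and bins of 5 kb 5. For Slc25a37 in R2R3_KO, DESeq2 gave 6, TMM factors 10, no filter 17, bins of 5 kb 24 and the local scale 11. The local scale gave 5 Hbb regions.

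Leaving out 1 library gave 33 to 59 fragments at Hba in R2R3_KO, 0 to 1 and 0 to 3 at Hbb in R1R2_KO and R2R3_KO, and 0 to 22 and 29 to 61 at Slc25a37. It gave 0 to 2 Hbb regions and 1 to 6 Slc25a37 regions; where a knockout library was left out these count that knockout alone, so 2 Hbb regions without R1R2_KO library 2 stand against 0, and 1 Slc25a37 region without R1R2_KO library 3 against 2. The Hba share at 100 to 500 kb in R1R2_KO less control was 2.57 to 2.97 points. Log2 changes ran from -0.036 to 0.085 for Rm in R2R3_KO, -0.094 to 0.0075 and -0.020 to 0.083 for the Hbb 5-prime side in R1R2_KO and R2R3_KO, and -0.0080 to 0.082 for the Slc25a37 far side in R1R2_KO.

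These log2 changes reversed. Rm in R2R3_KO gave -0.0181 with the whole-genome scale, -0.40 with reads outside all regions, -0.0177 with the 5 kb exclusion zone, -0.042 with 1 kb added and -0.11 under the 30% rule. With the whole-genome scale far upstream gave -0.0044 between the knockouts and the Hbb 5-prime side -0.12 in R2R3_KO. With reads outside all regions, R1R2_KO gave -0.11 far upstream, -0.38 at the upstream genes, -0.31 downstream, -0.085 on the Slc25a37 far side and -0.088 at its gene body. R2R3_KO gave -0.28 at the upstream genes, -0.33 downstream and -0.13 on the Hbb 5-prime side, which was -0.015 with the 5 kb zone, and the upstream genes between the knockouts gave 0.10. With the local scale, R1R2_KO gave 0.024 at the Hbb embryonic genes, 0.056 at the locus control region and 0.13 on the 5-prime side, and R2R3_KO gave 0.021 at the 3-prime boundary and 0.0100 at the Slc25a37 gene body.

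The cluster in single libraries, in percent of the other single knockouts, was 93.5 in R1_KO, 128 in R2_KO, 95.5 in R3_KO, 101 in Rm_KO, 84.0 in R4_KO and 53.6 in ES cells with the whole-genome scale, and 84.3, 117, 98.5, 115, 87.4 and 31.5 with reads outside all regions. With the 5 kb zone it was 109 in R2_KO, 94.1 in R4_KO and 37.4 in ES cells. Less the Rm and R4 blocks it was 86.9 in R1_KO, 102 in R2_KO, 99.3 in R3_KO, 110.3 in Rm_KO, 102 in R4_KO and 37.2 in ES cells, and with the whole-genome scale too 91.9, 121, 92.6, 106, 90.1 and 51.8. The Hbb locus control region in R1_KO was 89.5 without fragments that ES cells lack.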

Other observations

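The strain variant test in this part was written before its result was seen; the splits of the libraries, the depth test and the comparison across viewpoints were chosen after.

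Of the single knockouts, R1_KO held the least contact between the α-globin promoters and each of the other elements, relative to chromosome reads. In R1_KO, R2 held 1599 reads per 100000 chromosome reads, R3 970, Rm 968 and R4 1630, each below the values of the same element in R2_KO, R3_KO, Rm_KO and R4_KO wherever those keep it. In R2_KO, R4 held 2226 and Rm 1269, each above its values in the other single knockouts. ES cells held 204 at R1, 424 at R2, 461 at R3, 403 at Rm and 823 at R4. Each group is 1 library, so none of these orders has a replicate check, and R1_KO lay below and R2_KO above the mean of the others at the other viewpoints too. Less the mean of the Hbb locus control region and the Slc25a37 upstream region, the log2 level of the cluster was -0.55 in R1_KO, -0.71 in R2_KO and -0.51 in R3_KO. With the whole-genome scale and the Rm and R4 blocks left out, the cluster was 91.9% of the other single knockouts in R1_KO, 92.6% in R3_KO and 90.1% in R4_KO, so R1_KO was not lowest.

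The R1R2_KO library 1 lost a part of the Hbb fragments that the other R1R2_KO libraries held. In the window first looked at, 18 were lost and 42 were not. The chi-square over degrees of freedom of library 1 against the other R1R2_KO libraries was 7.98 and 7.57, against 1.75 between them. Low depth is argued against, since it held 1.21 times the chromosome reads, leaving out 2 kb around the viewpoints, of the deeper of them. A strain variant against the reference could remove such fragments. Outside the window first looked at, 9 of 9 lost fragments (100%) held under 50% of the other single knockouts in R1_KO, against 6 of 184 other fragments. This met the share that the prediction asked for, but the prediction did not state the 50% threshold. At 15%, the cut that defined loss in R1R2_KO library 1, it was 5 of 9 (55.6%) against 1 of 184. That share lies between those set beforehand for and against a variant, so at this cut the test decides nothing. These fragments are linked at 1 locus, in 1 library each of R1R2_KO and R1_KO. They are not independent observations, so no p-value is given. ES cells, from a 129/Ola line, also lost 9 of 9 at 50%, against 63 of 184 others, and 8 of 9 at 15%, against 10 of 184; the labels give both knockouts the same F1 strain, no genotype was read, and a shared parent line stays a hypothesis.

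The lower cluster contact of R2R3_KO came with like falls at Hbb and Slc25a37. The log2 change of the Hba cluster less the mean of the Hbb locus control region and the Slc25a37 upstream region was 0.0068 (SE 0.07) in R2R3_KO, with an exact permutation p of 0.8 over library values, so fewer near reads at every viewpoint in these libraries could account for that fall with chromosome reads as the scale. In R1R2_KO it was -0.53 (SE 0.07, exact permutation p = 0.1, the smallest possible), which argues against the same account of the fall without R1 and R2. The R2R3_KO libraries lay 0.54 above the R1R2_KO libraries on this measure (exact permutation p = 0.1). The SEs treat the viewpoints as independent, while the permutation tests use the value of each library. Slower erythroid maturation could also act at all 3 viewpoints, was not tested and stays open, as does a batch. The headers number R1R2_KO and control on from each other and R2R3_KO again from 1, and a run of its own cannot be told apart from the knockout.

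Splitting 6 libraries into 3 and 3 gives 10 splits, too few for a share under 0.05. Each other split also mixes the compared groups in both arms, so a group difference enters the spread and lowers its count. The splits therefore cannot decide whether the real counts arose by chance. For Hba, only 1 split, the real one, reached 108 fragments in R1R2_KO, 60 in R2R3_KO and 33 between the knockouts, and the highest other split gave 0 each time. At Hbb the real R2R3_KO split gave 6 and the highest other 0, while all 10 splits of R1R2_KO and control gave as many as the real count of 0. At Slc25a37 the real split gave 9 in R1R2_KO, the highest other 2, and 46 in R2R3_KO, the highest other 0.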
